A study of Rattus norvegicus with 16 samples.

How the data were processed

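The samples were 16 ovaries of female Jcl:SD rats, a Sprague-Dawley stock, in a design of genotype by treatment with 4 animals in each of 4 groups. Total RNA was prepared by the authors with the RNeasy Mini kit, labelled with Cy3 by the Low Input Quick Amp method, and hybridised to a single-colour Agilent whole-genome rat array. Spot signals were made by the authors with Agilent Feature Extraction, given as 10.7 in the sample descriptions and 10.7.1.1 in the files. The processed signal is an intensity that was, per the file headers, background-subtracted and detrended within each array, with low values replaced by a surrogate, and without scaling between arrays. The mean spot signal and the local background used in an alternative below are also intensity values per the file headers. The deposited value table holds log2 values. Compared spot by spot for probes printed once, each of its columns equalled the log2 processed signal minus a constant for the array, with a Pearson r of 1.0 and an SD of the difference of 0. The authors' labels give no statistical test.

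An array carried 62976 spots and 45598 non-control probes, of which 12 were left out because a spot had been marked as non-uniform or as a population outlier so that no usable spot remained on an array. Spots of the same probe were averaged. The log2 processed signal minus the 75th percentile of the array over non-control probes is called the log2 signal here. A probe was kept if it was well above background in at least 3 of the 4 arrays of at least 1 group, which left 26820 probes. Probes were named through their transcript accession (21229 probes), a current gene symbol (9328) or an older symbol of a single gene (321) in a RefSeq gene table for the rat. A further 5270 kept the name given in the file and 9450 had none. A gene with several probes was represented by the probe with the highest mean over the 16 arrays, and a probe without a name stood for itself. This gave 20094 tested features, called genes below, of which 14470 had a symbol and 5156 had more than 1 probe.

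Probe positions are those of the array files, whose headers name the rat build rn4. Some probes carry transcript accessions newer than that build, and the positions were not checked against a genome.

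Differences were fitted with limma 3.58.1 in R 4.3.3, as a model with a mean for each of the 4 groups over all 16 arrays (12 residual degrees of freedom, 2.43 prior degrees of freedom). There were 6 comparisons. These were olaparib against vehicle in wild-type rats, the same in BRCA1+/- rats, the mean of both, BRCA1+/- against wild-type with vehicle, the same with olaparib, and the interaction, which is the olaparib difference in BRCA1+/- minus that in wild-type. The comparisons share groups and are not independent. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Limma's moderated test is two-sided. Standard errors (SE) and intervals of 95% are those of limma, and SD is the spread of the 4 arrays of a group. A difference between a group above background and a group with no array well above background is given as a lower bound on the fold. For it the dim arrays were raised to the lowest signal called well above background on each array. Where only some arrays of a group were well above background, the plain difference is given, and its size rests partly on dim signals.

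A set of 31 gene lists for cell types of the ovary and its surroundings, for DNA repair and for stress and signalling responses was written before the data were examined. Each was tested with camera in limma, which compares the genes of a list with all other genes, at a preset correlation between genes of 0.01. A list was called at an adjusted p under 0.05 over the 31 lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. A list score is the mean of a list's log2 signals after each gene was centred over the 16 arrays. Scores and single values were compared with two-sided exact permutation tests, which for 4 against 4 arrays cannot give a p below 0.0286. The olaparib differences of both genotypes were correlated across genes, with an exact two-sided permutation of the treatment labels within each genotype.

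The genes named in the text were set by a rule made before the data were examined. It takes Brca1, the gene of the genotype, and Parp1, Parp2 and Parp3 first. For each comparison with called genes it takes the 12 most changed in each direction. Where fewer than 5 in a direction qualify, it takes the 5 symbols with the smallest unadjusted p, as values that did not pass. For the interaction and for both genotypes together it takes 5 in each direction. From each gene list it takes up to 4 members with the smallest unadjusted p. Genes named outside this rule are stated as such.

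The array files place the samples on 2 slides. Replicates 1 and 2 of every group were on slide 1 and replicates 3 and 4 on slide 2. On both slides each group had a column of its own, so that column and group cannot be told apart. Score differences of called lists within each slide are given beside the pooled ones, while single genes are given within slides only in part. A fit with the slide as a block was run, and the replicate number, which also fixes the slide and the place on it, was used as a block in another.

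The model was run on simulated data made from these arrays by adding known changes to 66 or 67 genes at each of 3 sizes. Group means were removed first, so unchanged genes had no difference between groups and no false call was possible. Control of false calls was therefore not tested. The estimates of changed genes equalled the added changes, so the shares below leave out sampling error and do not measure power in new samples. Added log2 changes of 1, 2 and 3 were recovered for 16.4%, 59.7% and 75.8% of genes for olaparib in wild-type rats and for 0%, 32.8% and 68.2% for the interaction. The median half-width of the 95% interval of a log2 difference was 0.633 for comparisons of 2 groups, 0.447 for olaparib over both genotypes and 0.895 for the interaction. The number of arrays limits the precision.

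Alternatives planned before the data were examined were normexp background correction with an offset of 50, quantile normalization, median scaling, the deposited value table, no filter on dim probes, only probes well above background on all 16 arrays, and the mean of a gene's probes. Further ones were the slide or the replicate number as a block, eBayes with trend and robust, array weights, only the groups compared, an added limit of 1 on the absolute log2 difference, and leaving out each array in turn. A pair of alternatives was chosen after seeing the data: leaving out 6 arrays with a high score of the oviduct list, and that score as a covariate.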

Results

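Gene expression was measured in the ovaries of 16 female rats with single-colour whole-genome arrays, with 1 array per animal. The groups were wild-type with vehicle, wild-type with olaparib, BRCA1+/- with vehicle and BRCA1+/- with olaparib, each with n = 4. Olaparib is a drug that inhibits the poly(ADP-ribose) polymerases PARP1 and PARP2, and BRCA1+/- rats carry a single intact copy of Brca1, a gene of homologous recombination repair. The drug was injected subcutaneously once daily for 14 days at 50 mg/kg from 3 weeks of age, and the ovaries were taken 24 h after the last injection. The composition of the vehicle, and the injection scheme, age and time of sampling of the vehicle animals, were not given in the sources used here, so it is not known whether they were matched. The 75th percentile of the processed signal ranged from 202 to 566 between arrays, and 55.5% to 60.7% of probes were well above background. No spot was saturated, and the median variation between spots of the same probe was 3.38% to 4.69%. Pearson correlations between pairs of arrays ranged from 0.902 to 0.992. The leading principal component held 41.98% of the variance and the next 13.94%. Values of the leading component were positive, from 27.9 to 107.99, on the 6 arrays with a high score of the oviduct list. They were negative, from -58.96 to -31.85, on the other 10. Between the slides 1594 genes were called and 4804 had an unadjusted p under 0.05. Each group had 2 arrays on each slide.

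Brca1 was read by a probe at position 90512623 to 90512682 of chromosome 10 that was well above background on all 16 arrays. Its mean log2 signal was -0.44 ± 0.36 (SD, n = 4) in wild-type with vehicle and -0.56 ± 0.50 (SD, n = 4) in wild-type with olaparib. In BRCA1+/- it was -1.11 ± 0.31 (SD, n = 4) with vehicle and -0.72 ± 0.36 (SD, n = 4) with olaparib. With vehicle the genotype difference was -0.67 (95% interval -1.26 to -0.09). Its unadjusted p was 0.0264 and its adjusted p 0.861, so it did not pass. The exact permutation p was 0.0571, and 3 of the 4 BRCA1+/- arrays lay below all wild-type arrays. Within the slides the difference was -0.73 on slide 1 and -0.61 on slide 2. With olaparib the genotype difference was -0.16 (95% interval -0.74 to 0.42), and it changed sign to 0.09 without WT olaparib replicate 3 and to 0.16 without 6 arrays chosen after seeing the data. The olaparib difference was -0.12 in wild-type (-0.62 on slide 1 and 0.39 on slide 2) and 0.40 in BRCA1+/-, neither called. A second Brca1 probe was well above background on 3 arrays and was not used. The position of the genotype's change relative to the probe was not given in the sources used here, so the probe may not report the changed copy.

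The PARP genes lay at log2 signals of 4.31 ± 0.14 for Parp1, 1.09 ± 0.49 for Parp2 and 1.66 ± 0.72 for Parp3 in wild-type with vehicle (SD, n = 4 each). None of them was called in any comparison. For Parp1 the olaparib difference was -0.22 in wild-type (95% interval -0.56 to 0.11) and 0.11 in BRCA1+/- (95% interval -0.23 to 0.44). For Parp2 it was -0.34 and 0.23, and for Parp3 -0.55 and 0.56. The smallest unadjusted p under these comparisons was 0.0728, for the Parp3 interaction of 1.11 (95% interval -0.12 to 2.33), which was -0.01 within slide 1 and 2.23 within slide 2. Among the genotype differences with olaparib, that of Parp1 was 0.07 and became -0.03 without WT olaparib replicate 1, and that of Parp3 was 0.33 and became -0.39 without the same 6 arrays.

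**Figure D1:**
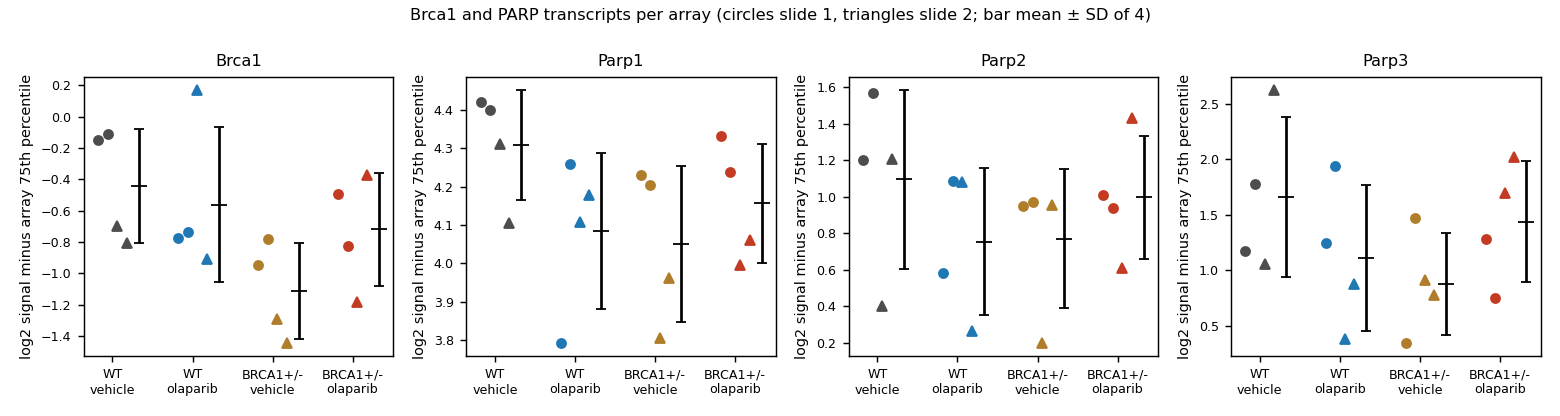
Log2 signal of Brca1, Parp1, Parp2 and Parp3 relative to the 75th percentile of each array, for the 4 groups, with a circle (slide 1) or triangle (slide 2) per array and bars for the mean ± SD of 4 arrays. The BRCA1+/- vehicle arrays lay between -1.44 and -0.78 for Brca1 and the wild-type vehicle arrays between -0.81 and -0.11.

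Olaparib against vehicle in wild-type rats asks what the drug alone does to ovarian expression. Limma called 0 of 20094 genes (lowest adjusted p 0.965). An unadjusted p under 0.05 was found for 867 genes, 454 higher and 413 lower, where chance gives 1005. The genes with the smallest p did not pass. Higher with olaparib were Slc37a1 (0.90 ± 0.20, log2 difference ± SE, by a probe whose companion gave 0.11), Hspa4l (2.06 ± 0.48), H19 (1.63 ± 0.39), Rbp7 (1.90 ± 0.48) and Akr1d1 (at least 2.02-fold). Lower were Saal1 (-1.91 ± 0.38), Adamts3 (-2.04 ± 0.50, second probe -0.81), Kif26b (at least 2.2-fold), Prp2 (at least 2.07-fold) and Olfm4 (at least 3.61-fold).

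Of the 31 gene lists, 6 were called for olaparib in wild-type rats at the preset correlation, 4 higher and 2 lower, and 0 with an estimated correlation or with fry. The list of oviduct and ciliated epithelium was higher in all 18 tested genes, with a median log2 difference of 2.74 (adjusted p 6.47e-13, and 0.526 with the estimated correlation). Its score differed by 2.24 on slide 1 and 3.43 on slide 2 (exact permutation p 0.0857). WT olaparib replicates 1 and 3 carried the difference, with scores of 3.47 and 3.25, while replicates 2 and 4, at -1.63 and -0.70, lay among the low arrays. Members were Cdh1 (2.02 ± 0.68), Rsph1 (3.26 ± 1.45), Tppp3 (3.04 ± 1.55) and Dnai1, which was well above background on no wild-type vehicle array. The list of adipocytes of the surrounding fat pad had a median of 1.25 (adjusted p 1.95e-07, and 0.486 with the estimated correlation). Its score differed by 2.91 on slide 1 and 0.30 on slide 2. Here replicates 1 and 2 were high, with scores of 2.46 and 1.72, against 0.06 and -1.36 on replicates 3 and 4. Its members Acvr1c (3.03 ± 0.85), Thrsp (4.28 ± 1.53), Adipoq (5.21 ± 2.04) and Lep, at background in wild-type with vehicle, were higher, and Acvr1c passed when adjusted over the list alone. No other member named for olaparib in wild-type passed in this way. Acvr1c, Thrsp and Adipoq were each well above background on only 2 of the 4 wild-type vehicle arrays, so their sizes rest partly on dim signals. The oviduct and adipocyte lists kept their calls without any single array, but each rests on 2 of the 4 olaparib arrays. The surface epithelium and mesothelium list (median 0.81, adjusted p 0.00203), with Wt1 and Krt18, lost its call without WT vehicle replicate 3 (0.59) or WT olaparib replicates 1 (0.46) or 2 (0.43). The macrophage list (-0.51, adjusted p 0.00656), with Msr1, Tyrobp and Cd163, lost its call without WT vehicle replicate 2 (-0.36) or WT olaparib replicates 3 (-0.21) or 4 (-0.37). The homologous recombination list (-0.17, adjusted p 0.0369), with Rnf8 and Eme1, lost it without WT vehicle replicates 1 or 2 or WT olaparib replicates 1, 2 or 4, with medians of -0.13, -0.13, -0.10, -0.20 and -0.17. The immediate early genes (0.15, adjusted p 0.0369), with Nr4a3 and Fos, lost it without WT vehicle replicates 1 or 3, WT olaparib replicates 2, 3 or 4 or BRCA1+/- vehicle replicate 3, with medians of -0.02 to 0.25. Scores differed on slides 1 and 2 by 1.68 and 0.17 for surface epithelium, 0.07 and -0.87 for macrophages, -0.43 and 0.08 for homologous recombination and -0.01 and 0.57 for immediate early genes, so the last 3 turned between the slides. So did Fos, with -0.06 and 2.78. Without 6 arrays of high oviduct score, chosen after seeing the data, the macrophage (-0.19) and surface epithelium (0.00) calls ended. The oviduct list, by which these arrays were chosen, is not judged by their removal.

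**Figure D2:**
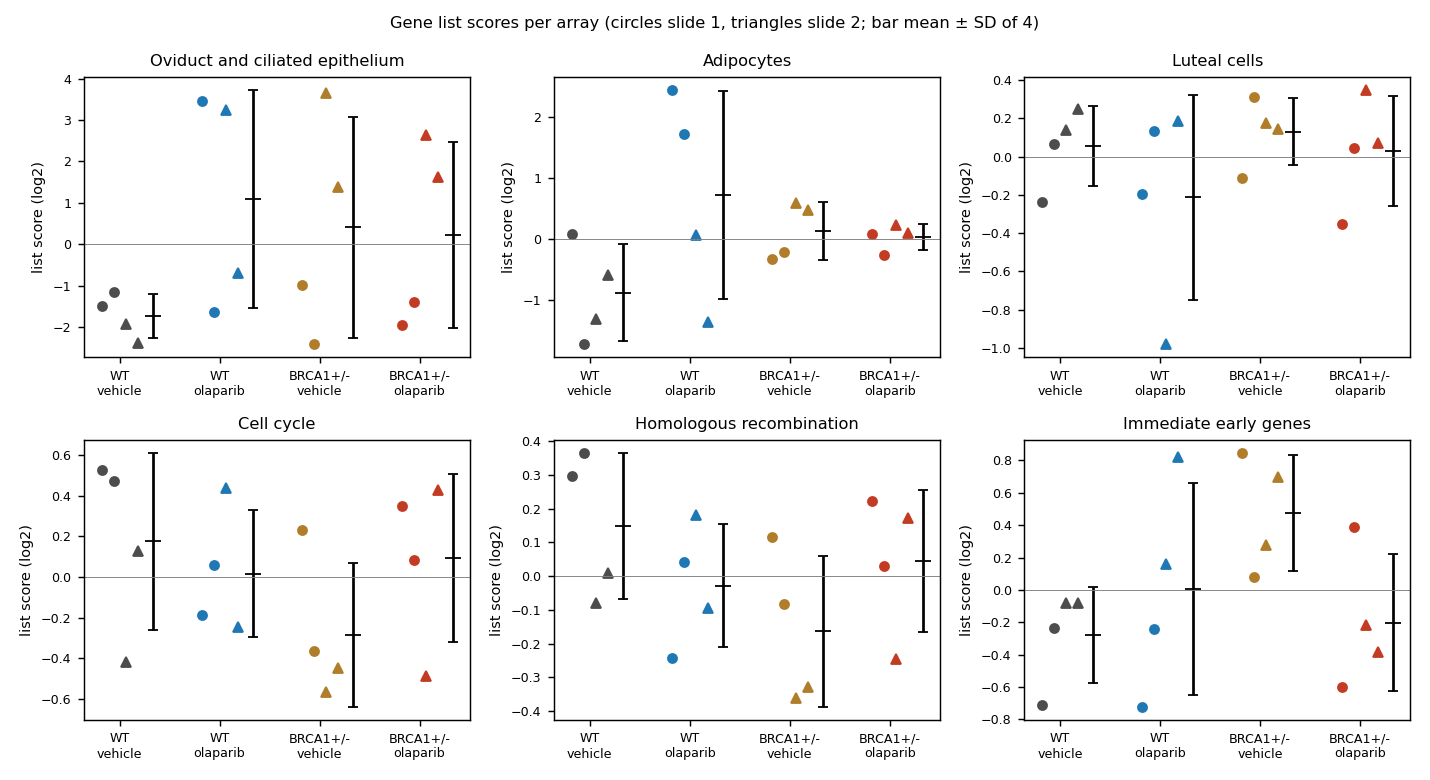
Scores of gene lists on the 16 arrays, as the mean of gene-centred log2 signals, by group, with a circle (slide 1) or triangle (slide 2) per array and bars for the mean ± SD of 4 arrays. The oviduct score lay between 1.39 and 3.65 on 6 arrays and between -2.41 and -0.70 on the other 10.

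Olaparib against vehicle in BRCA1+/- rats asks the same where a copy of Brca1 is lost. Limma called 0 genes (lowest adjusted p 1), and 234 had an unadjusted p under 0.05, 127 of them lower. The genes with the smallest p that were higher were Tvp23a (1.39 ± 0.37, log2 difference ± SE), Defb29 (1.20 ± 0.32), Mro (1.15 ± 0.33), Nsmce2 (0.78 ± 0.24) and Homer3 (1.59 ± 0.51, other probes 0.84 and 0.23). Lower were Tbx20 (at least 3.92-fold), Odaph (-3.53 ± 0.98), Rgs2 (-1.08 ± 0.35), Treml1 (at least 1.97-fold) and Cidea (-1.01 ± 0.34). Tvp23a and Nsmce2 were well above background on only 1 and 2 of the BRCA1+/- vehicle arrays, so their sizes rest partly on dim signals. Without WT olaparib replicate 4, on which Tbx20 was high, Tbx20 passed with an adjusted p of 0.048 (0.048 to 1 over all alternatives), the only call made for a gene when arrays were left out in turn.

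In BRCA1+/- rats 9 lists were called for olaparib, 4 higher and 5 lower, and 0 with an estimated correlation or with fry. The cell cycle and proliferation list was higher in 45 of 48 genes, with a median of 0.35 (adjusted p 7.82e-13, and 0.687 with the estimated correlation). Its score differed by 0.28 on slide 1 and 0.48 on slide 2 (exact permutation p 0.257). Members were Mcm3 (0.72 ± 0.28), Rrm2 (0.82 ± 0.37), Rrm1 (0.43 ± 0.19) and, in the other direction, Aurka (-0.97 ± 0.41). No member named for a list in this comparison passed, over all genes or over its list alone. The immediate early list was lower in 22 of 23 genes, with a median of -0.47 (adjusted p 2.06e-09, and 0.508 with the estimated correlation). Its score differed by -0.57 and -0.79 within the slides (exact permutation p 0.0857). Fosb (-2.25 ± 0.93), Fos (-1.74 ± 0.72), Fosl1 (-2.63 ± 1.19) and Ier3 (-0.66 ± 0.34) belonged to it. Homologous recombination genes such as Rad54l had a median of 0.20 (adjusted p 1.21e-05, 35 of 42 higher), and T and NK cell genes such as Il2rb one of -0.34 (adjusted p 7.9e-05, 16 of 18 lower). These 4 calls held without any single array. The homologous recombination score shared the sign of the cell cycle score on each of the 16 arrays, so these calls are not separate results. The red blood cell list (-0.55, adjusted p 7.65e-06), with Hbb-b1, was not called without BRCA1+/- olaparib replicate 2 (-0.22). The granulosa list (0.12, adjusted p 0.0134), with Fst and Inhbb, was not called without BRCA1+/- vehicle replicate 3 (-0.01) or BRCA1+/- olaparib replicate 2 (0.07). Endothelium (-0.24, adjusted p 0.0164), with Cldn5, was not called without BRCA1+/- vehicle replicates 1, 2 or 4 or BRCA1+/- olaparib replicates 1 or 3, with medians of -0.22 to -0.13. Growing-follicle oocyte genes (-0.21, adjusted p 0.0199), with Padi6, were not called without BRCA1+/- vehicle replicates 1, 2 or 3 or BRCA1+/- olaparib replicate 3, with medians of -0.23 to 0.03. Base excision repair genes (0.13, adjusted p 0.0277), with Lig1, Fen1 and the opposite Tnks, were not called without BRCA1+/- vehicle replicates 2, 3 or 4 or BRCA1+/- olaparib replicates 2 or 4, with medians of 0.06 to 0.17. Score differences on slides 1 and 2 were 0.11 and 0.31 for homologous recombination, -0.41 and -0.36 for T and NK cells, -1.11 and -0.17 for red blood cells and 0.23 and 0.20 for granulosa cells. They were -0.16 and -0.23 for endothelium, -0.24 and -0.13 for growing-follicle oocytes and 0.04 and 0.24 for base excision repair. Without the 6 arrays the calls of homologous recombination (0.11), base excision repair (0.05) and endothelium (-0.24) ended.

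Over both genotypes together, limma called 0 genes for olaparib (lowest adjusted p 1), and 263 had an unadjusted p under 0.05, 82 higher and 181 lower. Those with the smallest p that were higher were Akr1d1 (well above background only in wild-type with olaparib, and -0.02 after normexp background correction), Zfhx4 (0.71 ± 0.22, log2 difference ± SE), Il33 (0.74 ± 0.24), Mybl1 (0.46 ± 0.15) and Slc37a1 (0.45 ± 0.14, with the second probe at -0.38). Lower were Prp2 (well above background on no array of wild-type with olaparib), Hgf (-0.75 ± 0.20), Adamts3 (-1.29 ± 0.36, second probe -0.32), Naa11 (-1.15 ± 0.36) and Or2ak6 (-0.51 ± 0.16). Of the lists 10 were called, 5 in each direction, and 0 with an estimated correlation or with fry, and none of their members passed. Oviduct (1.34, adjusted p 1.31e-07), adipocyte (0.62, adjusted p 0.00029) and surface epithelium (0.47, adjusted p 0.000128) were higher without any single array too, with Dnai1, Acvr1c and Wt1 as members. The oviduct and adipocyte differences came from wild-type rats alone, since the medians in BRCA1+/- were -0.13 (14 of 18 genes lower) and -0.02 (8 of 16 lower). The exact permutation p of these scores was 0.249, 0.199 and 0.249. The adipocyte score differed by 1.55 on slide 1 and -0.04 on slide 2. Macrophages (-0.24), with Tyrobp, lost the call without WT vehicle replicate 2, WT olaparib replicates 3 or 4 or BRCA1+/- olaparib replicate 1 (-0.20 to -0.14). Red blood cells (-0.27), with Hba-a3 and Hbb-b1, lost it without WT vehicle replicate 4, WT olaparib replicate 4, BRCA1+/- vehicle replicate 3 or BRCA1+/- olaparib replicate 2 (-0.32 to -0.17). The cell cycle list (0.08) lost it without WT vehicle, WT olaparib or BRCA1+/- vehicle replicate 3 or BRCA1+/- olaparib replicate 4 (0.00 to 0.03). Cholesterol synthesis (0.24), with Pmvk, lost it without WT vehicle replicates 2 or 3, WT olaparib replicates 2 or 4, BRCA1+/- vehicle replicate 3 or BRCA1+/- olaparib replicate 1 (0.04 to 0.16). Endothelium (-0.22) lost it without WT vehicle replicates 3 or 4, WT olaparib replicate 3, BRCA1+/- vehicle replicate 4 or BRCA1+/- olaparib replicates 1 or 3 (-0.20 to -0.09). T and NK cells (-0.20), with Cd3g, lost it for 10 of the 16 arrays and growing-follicle oocyte genes (-0.18) for 9. Score differences turned between slides 1 and 2 for the cell cycle (-0.14 and 0.36) and growing-follicle oocytes (-0.50 and 0.16). They were 1.14 and 1.52 for oviduct, 1.15 and 0.12 for surface epithelium, -0.11 and -0.36 for macrophages and -0.50 and -0.47 for red blood cells. For cholesterol synthesis they were 0.38 and 0.04, for endothelium -0.12 and -0.25 and for T and NK cells -0.21 and -0.15. The red blood cell score is weighed down in part by Hba-a3 on some olaparib arrays. This gene was at -7.92, -7.71 and -7.86 on WT olaparib replicates 2 and 3 and BRCA1+/- olaparib replicate 2, and at 2.90 or more elsewhere. Other members moved too, since 14 of the 15 tested genes were lower with olaparib in BRCA1+/- rats. Without the 6 arrays the calls ended for the cell cycle (0.01), T and NK cells (-0.08), surface epithelium (0.24) and endothelium, which turned to 0.10.

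Across genes, the olaparib differences of the 2 genotypes had a Pearson r of -0.148 and a Spearman rho of -0.166. The exact permutation p over the 4900 arrangements was 0.567, and genes are not independent replicates. The sign depended on single arrays, since r was 0.32 without BRCA1+/- vehicle replicate 3, 0.11 without BRCA1+/- olaparib replicate 1 and 0.04 without BRCA1+/- olaparib replicate 2.

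BRCA1+/- against wild-type rats with vehicle asks what the loss of a copy of Brca1 does without the drug. Limma called 0 genes (lowest adjusted p 0.587). An unadjusted p under 0.05 was found for 1103 genes, 389 higher and 714 lower, against 1005 by chance. Genes with the smallest p that were higher in BRCA1+/- were Odaph (4.46 ± 0.98, log2 difference ± SE), H19 (1.76 ± 0.39), Chd7 (0.82 ± 0.18), Fpr1 (1.76 ± 0.41) and Arid5a (1.02 ± 0.24). Lower were Kcnt1 (-1.36 ± 0.27), Saal1 (-1.72 ± 0.38), Slc25a43 (-1.13 ± 0.26), Batf2 (-1.53 ± 0.36) and Fst (-1.11 ± 0.26). Fpr1 was well above background on only 1 wild-type vehicle array and Batf2 on 2 BRCA1+/- vehicle arrays, so their sizes rest partly on dim signals. H19 and Saal1 also stood out for olaparib in wild-type, a comparison that uses the same 4 wild-type vehicle arrays.

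With vehicle 11 lists were called between the genotypes, 8 higher and 3 lower in BRCA1+/-, and 0 with an estimated correlation or with fry. The cell cycle list was lower in 45 of 48 genes, with a median of -0.51 (adjusted p 2.78e-09, and 0.476 with the estimated correlation). Its score differed by -0.56 on slide 1 and -0.36 on slide 2 (exact permutation p 0.171). The median shrank to -0.24 without the 6 arrays of high oviduct score, which include BRCA1+/- vehicle replicates 3 and 4. This setting keeps BRCA1+/- vehicle arrays on slide 1 only, against wild-type arrays on both slides, so it mixes the genotype with the slide. Among members that did not pass, Tyms (-0.58 ± 0.23), Tk1 (-1.79 ± 0.73) and Mcm3 (-0.65 ± 0.28) went with the list and Aurka (1.19 ± 0.41) against it. The homologous recombination list was lower in 35 of 42 genes, with a median of -0.31 (adjusted p 7.57e-06, and 0.476 with the estimated correlation). Its score differed by -0.31 on each slide. Without the 6 arrays the median was -0.20 and the call ended (adjusted p 0.115), while with the oviduct score as a covariate it held. Rad54l (-0.64 ± 0.24), Fancb (-0.78 ± 0.30), Mdc1 (-0.51 ± 0.19) and Blm (-0.81 ± 0.32) belonged to it, and none passed. Immediate early genes had a median of 0.38 (adjusted p 1.2e-06, and 0.476 with the estimated correlation). Their score differed by 0.94 and 0.57 within the slides. Their score reached the smallest exact permutation p that 4 against 4 arrays can give, 0.0286. So did 2 lists that were not called, p53 targets (median -0.06, mean 0.11) and the glucocorticoid response (median 0.27). These exact p were not adjusted over the 31 lists. In the other comparisons of 2 groups, 0 lists had an exact p under 0.05. With so many tests, a few such values can arise by chance. Nr4a3 (1.99 ± 0.48), Ier3 (1.19 ± 0.34), Fosb (2.60 ± 0.93) and Fosl1 (3.33 ± 1.19) belonged to the immediate early list. Of these, Nr4a3 and Ier3 passed when adjusted over the list alone. The score of this list was highest on BRCA1+/- vehicle replicates 1 and 4 (0.85 and 0.70) and WT olaparib replicate 4 (0.82). It was 0.39 or less on all other arrays. The oviduct list (2.25, adjusted p 3.78e-08) differed by -0.39 on slide 1 and 4.67 on slide 2, with Cdh1 the 1 gene that passed over the list alone. T and NK cells (0.40, adjusted p 0.000297), with Gzmb and Il2rb, and adipocytes (0.90, adjusted p 0.000862), with Cidea, which passed over the list alone, and Adipoq, were higher. No other member of the called lists passed. These 6 calls held without any single array. Red blood cells (0.37), with Slc4a1, lost the call without WT vehicle replicate 3 (0.25). Base excision repair (-0.23), with Neil3 and Mutyh, lost it without WT vehicle replicates 2 (-0.16) or 4 (-0.21). Smooth muscle (0.33), with Kcnmb1, lost it without WT vehicle replicates 2 (0.18) or 3 (0.22). Growing-follicle oocyte genes (0.25), with Padi6, lost it without WT vehicle replicates 3 (0.22) or 4 (0.09) or BRCA1+/- vehicle replicate 1 (0.05). Endothelium (0.25), with Plvap and Cldn5, lost it without WT vehicle replicates 2 or 3 or BRCA1+/- vehicle replicates 1 or 4 (0.09 to 0.28). Score differences on slides 1 and 2 were 0.60 and 0.45 for T and NK cells, 0.55 and 1.49 for adipocytes, 0.64 and 0.27 for red blood cells and -0.18 and -0.27 for base excision repair. They were 0.20 and 0.45 for smooth muscle, 0.23 and 0.27 for growing-follicle oocytes and 0.38 and 0.02 for endothelium. The calls of base excision repair (-0.10), smooth muscle (0.00) and adipocytes (0.44) ended too without these arrays.

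BRCA1+/- against wild-type rats with olaparib asks whether the genotypes differ under the drug. Limma called 0 genes (lowest adjusted p 1), and 183 had an unadjusted p under 0.05, 110 higher and 73 lower. Genes with the smallest p that were higher were Defb20 (0.67 ± 0.17, log2 difference ± SE), Cst7 (1.30 ± 0.45), Tor3a (0.56 ± 0.19), Pcdhb5 (at least 1.74-fold) and 1700001K19Rikl (at least 1.35-fold). Lower were Kctd7 (-1.07 ± 0.30), Prss41 (-0.92 ± 0.28), Dip2b (-0.58 ± 0.18, second probe -0.15), Grifin (-1.50 ± 0.48) and Akr1d1 (at least 1.94-fold). Here 9 lists were called, 6 higher and 3 lower, 0 with an estimated correlation or with fry, none of their members passed, and each of the 9 lost its call without at least 1 array. Macrophages (0.38, adjusted p 3.47e-05), with Lyz2 and Clec10a, and the glucocorticoid response (0.32, adjusted p 0.00163), with Pdk4, Klf9 and Per1, lost it without WT olaparib replicate 3 (0.06 and 0.10). Adipocytes (-0.73, adjusted p 0.00163), with Lep, lost it without WT olaparib replicates 1 (-0.17) or 2 (-0.43). Oviduct (-0.87, adjusted p 0.00699), with Wfdc2, lost it without WT olaparib replicates 1 or 3 or BRCA1+/- olaparib replicates 1 or 2 (-0.30 to -0.01). The interferon (0.18) and immediate early (-0.21) lists, with Ifi44l and Btg2, lost it without WT olaparib replicates 3 or 4 or BRCA1+/- olaparib replicate 4, the interferon list also without WT olaparib replicate 2 or BRCA1+/- olaparib replicates 2 or 3 (0.07 to 0.20), and the immediate early list also without BRCA1+/- olaparib replicate 1 (-0.26 to -0.05). The NRF2 (0.18) and ovulatory (0.36) lists, with Akr1b8 and with Timp1 and the opposite Ptgs2 (-1.49 ± 0.96), lost it without WT olaparib replicate 3 (0.02 and -0.06) or BRCA1+/- olaparib replicates 1 or 4, and the ovulatory list also without BRCA1+/- olaparib replicate 2. Growing-follicle oocyte genes (0.21), with Zp2, lost it without BRCA1+/- olaparib replicates 1 (0.17) or 2 (0.07) and had a median of 0.04 without WT olaparib replicate 2 and -0.03 without replicate 4. Apart from the ovulatory list (0.26 and 0.35), all of these scores had opposite signs on slides 1 and 2. They were -0.33 and 1.06 for macrophages, -0.06 and 0.58 for the glucocorticoid response, -2.18 and 0.82 for adipocytes and -2.60 and 0.86 for oviduct. For interferon they were -0.28 and 0.67, for immediate early genes 0.38 and -0.79, for NRF2 -0.04 and 0.53 and for growing-follicle oocytes 0.75 and -0.31. Lyz2, Clec10a, Btg2 and Timp1 also turned between the slides. Without the 6 arrays only the growing-follicle oocyte (1.16) and immediate early (-0.35) calls held. The macrophage, NRF2, ovulatory and glucocorticoid medians turned (-0.11, -0.10, -0.26 and -0.17). In that setting the BRCA1+/- olaparib arrays were all on slide 1 and the wild-type ones on both slides, so the genotype is mixed with the slide.

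The interaction asks whether olaparib acts differently in BRCA1+/- rats. Limma called 0 genes (lowest adjusted p 0.969), and 692 had an unadjusted p under 0.05, 407 higher and 285 lower. The smallest p were found, on the higher side, for Saal1 (2.48 ± 0.54, log2 difference ± SE), Acot4 (1.58 ± 0.40), Defb20 (0.94 ± 0.24), Trmt6 (1.24 ± 0.33) and Kif26b, at background in wild-type with olaparib and BRCA1+/- with vehicle. On the lower side they were found for Hspa4l (-2.90 ± 0.68), H19 (-2.16 ± 0.56), Nr4a3 (-2.60 ± 0.68), Rbp7 (-2.52 ± 0.67) and Tbx20, at background in wild-type with vehicle and BRCA1+/- with olaparib. Of the lists 8 were called, 3 higher and 5 lower, and 0 with an estimated correlation or with fry. The cell cycle list had a median of 0.62 (adjusted p 1.29e-07), with a score difference of 0.85 on slide 1 and 0.23 on slide 2 and with Tyms and Pcna as members. Homologous recombination had a median of 0.3 (adjusted p 1.77e-05), with Eme1, Rad54l and Rnf8, and its score followed the sign of the cell cycle score on every array. Lower were the oviduct list (-3.03, adjusted p 7.97e-09), with Cdh1 and Dnah5, the immediate early genes (-0.62, adjusted p 4.68e-07), with Fos and Fosb, and adipocytes (-1.33, adjusted p 4.93e-06), with Lep. Over the list alone Nr4a3 passed among the immediate early genes, and no member of another called list. These 5 calls held without any single array. Base excision repair (0.33), with the opposite Macrod1 (-0.70 ± 0.30), lost the call without WT olaparib replicate 4 (0.35). T and NK cells (-0.36) lost it without WT vehicle replicates 1 or 4, WT olaparib replicate 4, BRCA1+/- vehicle replicate 2 or BRCA1+/- olaparib replicates 1 or 4 (-0.17 to -0.08). Red blood cells (-0.42) lost it without WT vehicle replicates 2 or 3, WT olaparib replicate 2, BRCA1+/- vehicle replicates 1 or 3 or BRCA1+/- olaparib replicate 2 (-0.38 to -0.17), and the score differed by -1.21 on slide 1 and 0.60 on slide 2. The other score differences on slides 1 and 2 were 0.54 and 0.23 for homologous recombination, -2.21 and -3.82 for oviduct, -0.56 and -1.36 for immediate early genes and -2.74 and -0.67 for adipocytes. They were 0.24 and 0.35 for base excision repair and -0.40 and -0.42 for T and NK cells. The base excision repair call ended without the 6 arrays (0.18).

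A further 12 lists were not called in any of the 6 comparisons. Their medians ranged from -0.06 to 0.02 for p53 targets, -0.09 to 0.05 for apoptosis, -0.20 to 0.25 for luteal cells, -0.16 to 0.21 for theca and steroid synthesis, -0.04 to 0.12 for hedgehog targets and -0.12 to 0.14 for oocytes of small follicles. They ranged from -0.12 to 0.17 for extracellular matrix, -0.16 to 0.17 for NF-kB and cytokines, -0.35 to 0.20 for the oestrogen and progesterone response, -0.07 to 0.09 for nerve, -0.12 to 0.37 for B cells and -1.21 to 0.98 for neutrophils and mast cells. Of the 186 tests of a list in a comparison, 32 had a median, mean and test that differed in sign, and 0 of these were called. When adjusted over the list alone, a gene passed in 6 of the 186 tests, and over all genes tested in 0.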

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

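The tests in this part of possible causes were chosen only after the result was seen. The comparisons of lone values and of the olaparib differences between genotypes followed rules set before the data were examined.

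In groups of 4 arrays, 576 sets of values were examined for a lone array, far from the other 3 of its group by Dixon's ratio. These were 110 named genes, 31 list scores and 3 array values. A lone value was found in 34 sets (5.9%), where chance gives about 1 in 20, so the number by itself says little. WT vehicle replicate 3 had the lowest share of probes well above background of its group, 55.52%, and the lowest 75th percentile, 7.68 on the log2 scale.

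The log2 signals far from the rest of their group were as follows. In wild-type with vehicle they were Akr1d1 (-6.19, replicate 3), Rsph1 (-0.32, replicate 2), Ifi44l (-1.18, replicate 2) and Fosl1 (-4.19, replicate 1). In wild-type with olaparib, replicate 4 was alone for Tbx20 (-4.18), Odaph (1.73), 1700001K19Rikl (-5.7), Ier3 (2.53) and Il2rb (-2.14) and for the nerve and Schwann cell score (-0.73). Replicate 3 was alone for Brca1 (0.17) and Chd7 (-2.88), replicate 2 for Slc25a43 (-2.46), Dip2b (-0.41) and Slc4a1 (-0.65), and replicate 1 for Defb29 (-4.39) and Prss41 (-4.55). In BRCA1+/- with vehicle, replicate 3 was alone for Parp2 (0.2), Kcnt1 (0.26), Tor3a (-1.64) and Ifi44l (-2.3). Replicate 1 was alone for Nsmce2 (-6.06) and Tk1 (2.62), replicate 2 for H19 (1.15) and replicate 4 for Clec10a (0.17). In BRCA1+/- with olaparib, replicate 2 was alone for Fosb (-2.34), Hba-a3 (-7.86), the red blood cell score (-1.53) and the score of oocytes of small follicles (0.15). Replicate 3 was alone for Kctd7 (-4.21) and Ifi44l (-1.68), and replicate 1 for Defb20 (-4.15).

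The olaparib difference of 8 gene lists differed between the genotypes by the interaction term, at the preset correlation. The medians were 0.62 for cell cycle, 0.3 for homologous recombination, 0.33 for base excision repair, -0.62 for immediate early genes, -0.36 for T and NK cells, -1.33 for adipocytes, -3.03 for oviduct and -0.42 for red blood cells. None was called with an estimated correlation or with fry.

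The oviduct and ciliated epithelium score was 1.39 to 3.65 on WT olaparib replicates 1 and 3, BRCA1+/- vehicle replicates 3 and 4 and BRCA1+/- olaparib replicates 3 and 4, and -2.41 to -0.70 on the other 10. The slide alone is argued against, since the highest score on slide 1 was 3.47, on WT olaparib replicate 1, and slide 2 held low wild-type arrays. The remaining high arrays were all on slide 2, and in BRCA1+/- the high arrays were exactly those of slide 2. A part played by the slide, or by how animals were placed on it, stays open. Oviduct tissue taken with the ovary is a candidate explanation. Of 43 further cilia and epithelial genes outside the list, 36 (83.7%) had the same 6 arrays as their highest, against 3.23% of all tested genes. On WT olaparib replicate 1 the listed genes Tppp3, Sntn, Tekt4 and Foxj1 had log2 signals of 6.86, 5.15, 4.15 and 4.06, against 1.61, -3.92, -2.89 and -3.89 on replicate 2. Of the 18 listed genes, 1 was also in another list and 12 were well above background on all 10 low arrays, where expression in the ovary itself and a smaller amount of oviduct tissue both stay open. Olaparib as the cause on all 6 arrays is argued against, since the highest score, 3.65, was on BRCA1+/- vehicle replicate 3, an animal without the drug. An effect of olaparib on part of them stays open, with an exact permutation p of 0.249 over both genotypes and 0.0857 in wild-type. In BRCA1+/- the score difference was -0.18 (p 0.943). A difference in dissection between animals stays open as well.

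WT olaparib replicate 3 had a Star signal of 0.51, where the other 15 arrays had 5.36 to 7.16, and 32 genes at least 3 log2 units below every other array, against 0 or 1 on the others. Star encodes the protein that brings cholesterol into steroid synthesis. Poor quality of the array is argued against, since 59.9% of its probes were well above background and the spread of replicate spots lay within the range of the others. Dilution by oviduct tissue is argued against too, since the other 2 arrays with an oviduct score within 0.5 had Star at 5.36 or more. Whether that ovary held little luteal tissue stays open. The luteal list without Ptgfr scored -0.68 on it, where the others had -0.28 to 0.27, but this restates the low luteal transcripts and decides nothing. Among other lists, the array also had the lowest scores for cholesterol synthesis (-1.21), macrophages (-1.13), the ovulatory response (-1.04), endothelium (-0.98) and NRF2 (-0.67). Lowest too were the glucocorticoid response (-0.575), theca and steroid synthesis (-0.49, with the next array at -0.47), extracellular matrix (-0.43) and apoptosis (-0.24). The array had the highest scores for growing-follicle oocytes (1.02), oocytes of small follicles (0.57) and hedgehog targets (0.34). It is a single animal, no difference named by the design was tested for it, and a mix-up with a sample outside the series was not excluded.

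The cell cycle list was lower in BRCA1+/- with vehicle and higher with olaparib in BRCA1+/-. Each group had 2 arrays on each slide, so a shift common to all arrays of a slide cancels from these differences by design. The score difference with vehicle was -0.36 within slide 2 and -0.56 within slide 1, so it did not come from 1 slide only. Dilution by oviduct tissue is partly mixed with the genotype, since 2 of the 4 BRCA1+/- vehicle arrays have the high oviduct score and no wild-type vehicle array does. On slide 1 all vehicle arrays had low oviduct scores, from -2.41 to -0.99, so the difference of -0.56 there did not come from arrays of high score. It rests on 2 arrays per group, so a part played by dilution in the pooled difference stays open. The median of -0.51 was -0.43 with the oviduct score as a covariate, and -0.24 without the 6 arrays. The BRCA1+/- vehicle group then held 2 arrays, both on slide 1, against wild-type arrays on both slides. The list was still called in that setting, with an adjusted p of 0.00724. Over all alternatives that adjusted p ranged from 2.7e-15 to 0.686, the highest with fry. The spread between animals stays open, since the exact permutation p of the score was 0.171. That test ignored the slide. Within each slide both BRCA1+/- vehicle arrays lay below both wild-type ones. Their scores were 0.23 and -0.36 against 0.53 and 0.47 on slide 1, and -0.56 and -0.45 against -0.42 and 0.13 on slide 2. With 2 arrays per group on a slide this order does not decide the question. An effect of the genotype itself stays open and is not shown, and the same holds for the interaction of 0.62.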

How the results depend on the processing

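The alternatives without 6 arrays of high oviduct score, and with that score as a covariate, were chosen after seeing the data. The others were planned. Without the 6 arrays the genotype comparisons are mixed with the slide, since the BRCA1+/- arrays left are all on slide 1. Fits with only the groups compared have no value for the mean of both genotypes and the interaction.

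The count of called genes was 0 in every comparison under every alternative other than leaving out single arrays. On leaving out each array in turn it ranged from 0 to 1 for olaparib in BRCA1+/- rats, where Tbx20 was called without WT olaparib replicate 4, and was 0 for the other comparisons. At an unadjusted p under 0.05 the comparisons had 183 to 1103 genes as reported, 244 to 1429 with the slide block, 390 to 1794 with the replicate block, 286 to 2254 with array weights, 189 to 745 without the 6 arrays and 245 to 931 with the covariate.

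The counts of called lists fell to 0 in all 6 comparisons with an estimated correlation and with fry. Both take into account that the genes of a list vary together between animals, which the preset correlation of 0.01 does not. The count for olaparib in wild-type rats rose from 6 to 10 without the 6 arrays, and for both genotypes together it fell from 10 to 5 with array weights; the cause was not tested. On leaving out each array in turn the counts ranged from 3 to 9 for olaparib in wild-type, 7 to 12 in BRCA1+/-, 5 to 11 in both, 7 to 12 for the genotype with vehicle, 6 to 13 with olaparib and 7 to 12 for the interaction. Large drops came without WT olaparib replicate 2 in the first (3 lists), without BRCA1+/- vehicle replicate 3 (5), WT olaparib replicate 4 (6) or BRCA1+/- olaparib replicate 1 (6) in both genotypes, and without WT vehicle replicate 3 for the genotype with vehicle (7). With the slide as a block they were 6, 9, 9, 11, 7 and 8, and with the replicate number 4, 8, 9, 11, 6 and 7. Of the 53 list calls, 20 held without any single array, 53 held with the deposited table, 50 with normexp and with the slide block, 49 with quantile normalization, 44 without a filter, 45 with the replicate block, 39 with array weights, 39 with the covariate and 29 without the 6 arrays.

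The replicate numbers were checked as possible pairs, for which every same-numbered pair would need a correlation over 0.1 of the deviations from the group means. Of 24 such pairs of arrays 13 had one, with a median of 0.207 and a range from -0.443 to 0.715, so the block is an alternative only. As a hint from the data, 12 of the 16 arrays correlated best with an array of their own number, and the median was 0.033 for other pairs on the same slide and -0.125 across slides. A number also marks the slide and the place on it, so this cannot be told apart from a position effect.

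The correlation of the olaparib differences ranged from -0.173 to -0.077 over the other settings and from -0.397 to 0.32 on leaving out arrays.

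Directions reversed for these values, with the cause not tested unless stated. For a list this means the direction of its test. Akr1d1 over both genotypes was -0.022 after normexp. For the genotype with olaparib, leaving out single arrays moved Brca1 between -0.273 and 0.087, Parp1 between -0.026 and 0.13, and the growing-follicle oocyte list between -0.026 and 0.657, where its test also turned at 0.035. Without the 6 arrays, Brca1 was 0.162, Parp3 -0.39, Timp1 -0.157 and Wfdc2 0.237, and the NRF2 and macrophage lists were -0.102 and -0.114. Over both genotypes the tests of the cell cycle and endothelium lists turned without these arrays, with medians of 0.008, which kept its sign, and 0.104. The oocyte list for olaparib in BRCA1+/- was 0.034 with array weights. Medians of some lists also changed sign as their call was lost on leaving out single arrays: to -0.022 for immediate early genes with olaparib in wild-type, to -0.011 for granulosa cells and 0.029 for growing-follicle oocytes with olaparib in BRCA1+/-, and to -0.06 for the ovulatory list between genotypes with olaparib. Without the 6 arrays the same held for the ovulatory (-0.262) and glucocorticoid (-0.168) lists between genotypes with olaparib and for the oviduct list between genotypes with vehicle (-0.149). With array weights it held for the cell cycle list over both genotypes (-0.004), growing-follicle oocytes between genotypes with vehicle (-0.047) and immediate early genes between genotypes with olaparib (0.076). With the oviduct score as a covariate the oviduct list itself was -0.084, -0.056 and 0.116 for olaparib in wild-type, olaparib in both genotypes and the genotype with olaparib, which the covariate brings about by construction, and it was not called, at -0.072 and 0.175, for the genotype with vehicle and the interaction.

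Signal over background limits what can be seen: 55.5% to 60.7% of probes were well above background on an array, and folds against a group below it are lower bounds.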

Other observations

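The splits of the arrays were planned before the data were examined. The split by slide and the splits balanced over the slides were added, and the genes in the last paragraph were chosen, after values had been seen.

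Other divisions of the same arrays into groups of the same sizes were fitted to ask how often they give as large a result. For olaparib in wild-type rats, 23 of 35 splits gave at least the 867 genes at an unadjusted p under 0.05, with up to 3310 in another split, and 30 of 35 gave at least the 6 called lists, with up to 16. For olaparib in BRCA1+/- rats, 27 of 35 splits gave at least 234 genes, with up to 3861, and 12 of 35 gave at least 9 lists, with up to 12. For olaparib over both genotypes, 92 of 100 drawn splits gave at least 263 genes, with up to 3284, and 30 of 100 at least 10 lists, with up to 17. For the genotype with vehicle, 10 of 35 splits gave at least 1103 genes, with up to 2336. With olaparib, 33 of 35 splits gave at least 183 genes, with up to 3907, and 24 of 35 at least 9 lists, with up to 17. For the interaction, 55 of 100 drawn splits gave at least 692 genes, with up to 3741, and 61 of 100 at least 8 lists, with up to 17. Chance cannot be excluded for any of these counts. Only for the 11 lists called between the genotypes with vehicle was the real split the sole one of 35, that is 1 of 35, with up to 10 lists in another split. This is the smallest share that 35 splits can give, for 1 of 12 counts examined. None of these 11 lists was called with an estimated correlation or with fry, and 7 lists were called without WT vehicle replicate 3, so the count is not read as beyond chance.

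The splits that gave several times the real count of genes point to a structure of the samples other than the groups. The leading principal component parted the 6 arrays of high oviduct score, which include WT olaparib replicate 1 on slide 1, from the other 10. The split that parts the slides gave 2759 genes among the wild-type arrays, 3861 among the BRCA1+/- arrays, 2336 among the vehicle arrays and 2351 among the olaparib arrays. It gave the highest count of any other split for olaparib in BRCA1+/- and for the genotype with vehicle. Another split gave more for olaparib in wild-type (3310) and for the genotype with olaparib (3907). Among the BRCA1+/- arrays the split by slide is also the split between high and low oviduct scores. The 3861 genes therefore cannot be assigned to the slide rather than to what the oviduct score reflects. With the slide as a block the real comparisons still called 0 genes, with 1131, 363, 361, 1429, 244 and 941 at an unadjusted p under 0.05 in the order above. Within each slide alone 0 genes were called in every comparison.

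Splits that keep 2 arrays of each slide in each group leave the slide out of the chance counts. For olaparib over both genotypes 85 of 100 drawn splits of this kind gave at least 263 genes, with up to 2077, and 46 of 100 at least 10 lists, with up to 21. For the interaction 42 of 100 gave at least 692 genes, with up to 2433, and 64 of 100 at least 8 lists, with up to 15. Chance cannot be excluded for these counts. A comparison of 2 groups has 18 such splits, too few for a share under 0.05. The highest other count was 2651 genes and 16 lists for olaparib in wild-type, 925 and 10 in BRCA1+/-, 1270 and 9 for the genotype with vehicle and 2135 and 17 with olaparib. The real counts were 867 and 6, 234 and 9, 1103 and 11, and 183 and 9.

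Some transcripts were far lower, or far higher, on a few arrays than on the others. Cyp17a1 had log2 signals of -1.57, -1.74 and -1.93 on WT vehicle replicates 2 and 4 and BRCA1+/- olaparib replicate 4, and of 3.70 to 6.41 on the other 13 arrays. The same 3 arrays had the highest Runx1 (1.81, 2.19 and 1.72) and Timp1 (6.90, 7.13 and 7.25). Hba-a3 was at -7.92, -7.71 and -7.86 on WT olaparib replicates 2 and 3 and BRCA1+/- olaparib replicate 2, and at 2.90 to 5.24 elsewhere. Kcne2 was at -3.75, -2.98 and -2.93 on replicate 2 of wild-type with olaparib, BRCA1+/- with vehicle and BRCA1+/- with olaparib, and at 3.69 to 5.69 elsewhere. Tex10 was at -7.43 on WT vehicle replicate 2 and -6.16 on BRCA1+/- olaparib replicate 4, and at 0.10 to 1.68 elsewhere. Edn2 was at 3.47, 3.12 and 3.93 on WT olaparib replicate 4 and BRCA1+/- vehicle replicates 1 and 4, and at 0.43 or less elsewhere. The same arrays had the highest Areg (1.05, 1.44 and 1.07) and the highest immediate early scores (0.82, 0.85 and 0.70). Whether the calls of the immediate early list come from what these arrays share was not tested.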
